A study of Homo sapiens with 6 samples.

How the data were processed

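ATAC-seq maps open chromatin: a transposase cuts accessible DNA and inserts sequencing adapters, so that stretches with many insertions stand out as peaks. It was run on LNCaP cells, an established androgen-sensitive line from human prostate cancer, carrying either a control hairpin (shCON) or a hairpin against the retinoblastoma protein RB (shRB). Per the labels' protocols, each reaction used 75000 cells and a transposition of 30 minutes at 37 °C. The 6 libraries form 3 groups of 2: shCON cells after 72 hours of CDT (the hormone-deficient condition), shCON cells given 72 hours of CDT and then 3 hours of dihydrotestosterone (DHT, an androgen), and shRB cells after 72 hours of CDT. Nothing in the labels says whether the 2 libraries of a group came from separate cultures.

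The deposited data used here are 3 peak lists, 1 per group, each named in the labels of both replicates of its group. Per the labels, the list names give a threshold of 0.1 on the irreproducible discovery rate (IDR) and steps of filtering, merging and scoring. The names also carry the abbreviation ppr, which no label explains. The genome build is hg19, per the submitters' processing notes. The aligner, the peak caller, the read filters and any shift of reads for the transposase offset are not given in the sources used here. Each list gives a chromosome, a start, an end and a whole-number score per peak. The deposited score runs from 413 to 1000 in every list, and 1000 is a cap reached by many peaks. The lower end lies next to 415, the value that the usual IDR scaling (minus 125 times the base-2 logarithm) gives at 0.1, but no header or label states how the authors computed the score. It was used only to rank and band peaks within a list. The lists hold no read counts, heights or summits, so sequencing depth is unknown, and a peak's absence from a list is not a measurement of low accessibility.

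Overlaps were computed with bedtools 2.31.1, and all other values with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was called shared with another list where it overlapped a peak of that list by at least 1 bp. Peaks linked by such overlaps across the 3 lists were joined into regions, and each region was classed by the lists with a peak in it. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Neighbouring peaks are not independent, and these intervals cover counting error only, not the spread between cultures. Chance overlap came from 100 random placements of a list on its own chromosomes, each taken to end at the last peak in any list. Score percentiles are ranks within 1 list, with an order-statistic 95% interval for medians. Ratios of peak numbers per chromosome carry exact conditional binomial intervals. Peak widths were compared at the regions with exactly 1 peak in every list. Surroundings were measured as the number of regions common to all 3 lists whose midpoint lay within 500 kb. The mean of this number was set against 10000 random sets of the same size drawn from the regions held by 1 list only. As regions cluster, these sets vary too little, so the difference was also given a 95% interval from 1000 bootstrap resamples of 595 blocks of 5 Mb. Code for classes, neighbour counts, matched sets and joint absence was tested on simulated data with planted answers and recovered 34 of 34.

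Since each list pools its 2 replicates, no difference between conditions can be compared with the spread between replicates, and no p-value is given. Comparisons were fixed before the data were examined: RB knockdown (shRB CDT with shCON CDT), androgen stimulation (shCON DHT with shCON CDT), and shRB CDT with shCON DHT. The rule for named regions, also fixed then, took the 5 highest-scoring peaks absent from the other list in each direction and the 3 highest-scoring peaks of each list. Because the score is capped, ties at 1000 were broken by width, wider first, a choice made after the data were examined. The rule's part for named genes, and the planned promoter, fixed gene list and sequence motif comparisons, were not run: they need an hg19 genome or annotation, and the gene table at hand is of GRCh38. That table was used only for the number of protein-coding genes on each chromosome. Positions are hg19 and counted from 1. Alternatives tried were a 50% reciprocal overlap, peaks within 500 bp counted as shared, the top 50% of each list by score, lists cut by score to the length of the shortest, autosomes only, and peaks reset to 500 bp around their midpoint. Where lists were cut, all measures, score percentiles included, were computed among the kept peaks only. A counterpart below the cut then did not count.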

Results

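Chromatin accessibility was mapped by ATAC-seq in LNCaP prostate cancer cells with a control hairpin (shCON) or an RB hairpin (shRB). The control cells were sampled without hormone (CDT) and after 3 hours of DHT, and the RB-depleted cells without hormone. Each of the 3 groups had 2 libraries, which the authors combined into 1 peak list. The shCON CDT list held 12096 peaks, the shCON DHT list 12896 and the shRB CDT list 14788. The peaks covered 11.7 Mb of the hg19 genome in shCON CDT, 10.3 Mb in shCON DHT and 15.0 Mb in shRB CDT. Median peak width was 937 bp in shCON CDT, 776 bp in shCON DHT and 992 bp in shRB CDT. The share of peaks at the score cap of 1000 was 32.5% (95% interval 31.7 to 33.3) in shCON CDT, 27.0% (26.2 to 27.7) in shCON DHT and 35.1% (34.3 to 35.9) in shRB CDT. Sequencing depth behind the lists is unknown.

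Joined across conditions, the peaks formed 21031 regions, of which 7149 (34.0%, 33.4 to 34.6) carried a peak in all 3 lists. The common regions were the widest, with a median of 1353 bp, in part by construction, since a region spans all its linked peaks. Another 4737 regions (22.5%) had a peak in shRB CDT only, 3297 (15.7%) in shCON DHT only and 2642 (12.6%) in shCON CDT only. This order depended on the list lengths: with each list cut by score to 12096 peaks, the numbers were 2817, 2947 and 2930. Regions in exactly 2 lists were fewer: 1400 were in shCON CDT and shRB CDT, 1241 in shCON DHT and shRB CDT, and 565 in shCON CDT and shCON DHT. In the top 50% of each list by score the order of the first pair of these classes turned, with 843 and 890 regions. The 3 highest-scoring peaks of each list, widest first, all lay in accessible sites of all 3 conditions. In shCON CDT these were on chromosome 8 from 101962556 to 101965419, on chromosome 5 from 113696499 to 113699282 and on chromosome 19 from 57348796 to 57351496. In shCON DHT they were on chromosome 6 from 157800978 to 157803468, on chromosome 4 from 52708715 to 52711077 and on chromosome 12 from 112035613 to 112037898. In shRB CDT they were on chromosome 16 from 54962392 to 54965327, on chromosome 8 from 103665951 to 103668858 and on chromosome 11 from 118306055 to 118308826.

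**Figure D1:**
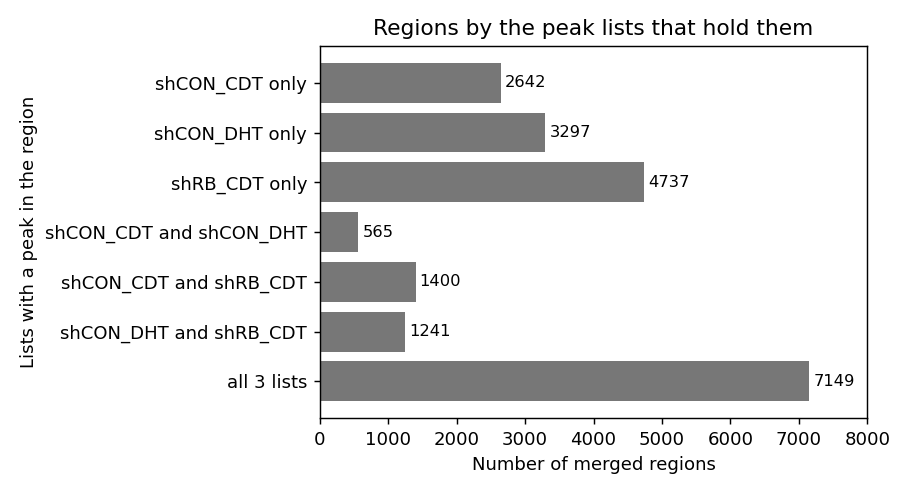
Bars give the number of merged regions (horizontal axis) for each combination of peak lists that hold them (vertical axis), with 1 list per condition. The bar for all 3 lists is the longest at 7149 regions, and among the regions of a single list shRB CDT has the most, 4737, but the fewest, 2817, with lists cut to one length.

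The first comparison asked whether the accessible sites of hormone-deprived cells differed after RB depletion. The shRB CDT list held 2692 more peaks than shCON CDT (22.3% more) and covered 28.3% more sequence. Of the shCON CDT peaks, 73.2% (72.4 to 74.0) were also in shRB CDT, against 1.13% for randomly placed peaks. In the other direction 59.1% (58.3 to 59.9) of shRB CDT peaks were in shCON CDT, against 0.923% at random. That left 6043 shRB CDT peaks with no counterpart in shCON CDT and 3240 shCON CDT peaks with none in shRB CDT. With both lists cut by score to 12096 peaks, these numbers were 3838 and 3696, although equal lengths bring both directions close by construction.

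The unshared peaks of this comparison mostly had low scores. Their median score percentile was 25.6 (24.9 to 26.4) within shRB CDT and 21.1 (20.3 to 21.9) within shCON CDT, while the median shared peak stood at the score cap in shRB CDT and at the 62.5 percentile in shCON CDT. At the score cap, 281 of 5192 shRB CDT peaks (5.41%, 4.81 to 6.06) were absent from shCON CDT, and 68 of 3931 shCON CDT peaks (1.73%, 1.35 to 2.19) were absent from shRB CDT. At the 6240 sites with exactly 1 peak in every list, shRB CDT peaks were 1.04 times (1.03 to 1.04) as wide as shCON CDT peaks at the median. The 5 top-ranked shRB CDT peaks without a shCON CDT counterpart lay on chromosome 12 from 1702277 to 1704588, chromosome 16 from 52579964 to 52581892, chromosome 17 from 78009135 to 78011061, chromosome 5 from 77943776 to 77945700, and chromosome 20 from 30605516 to 30607362. All but the chromosome 16 peak also overlapped a peak in shCON DHT, as did 183 of the 281 at the cap and 21.6% of all 6043. Of shRB CDT peaks in general, 93.1% at the cap and 57.9% of all overlapped a shCON DHT peak. The chromosome 16 peak was 507 kb from the nearest shCON CDT peak. The 5 top-ranked shCON CDT peaks missing from shRB CDT lay on chromosome 22 from 25348176 to 25349787, chromosome 1 from 101490745 to 101492313, chromosome 5 from 107007076 to 107008542, chromosome 7 from 130080330 to 130081573, and chromosome 19 from 58858205 to 58859385. The peaks on chromosomes 22, 1 and 7 were also in shCON DHT, whereas those on chromosomes 5 and 19 were in shCON CDT alone. Of all such shCON CDT peaks, 18.5% were in shCON DHT, and at the cap 33 of 68. Of shCON CDT peaks in general, 65.4% of all and 95.4% at the cap were in shCON DHT.

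**Figure D2:**
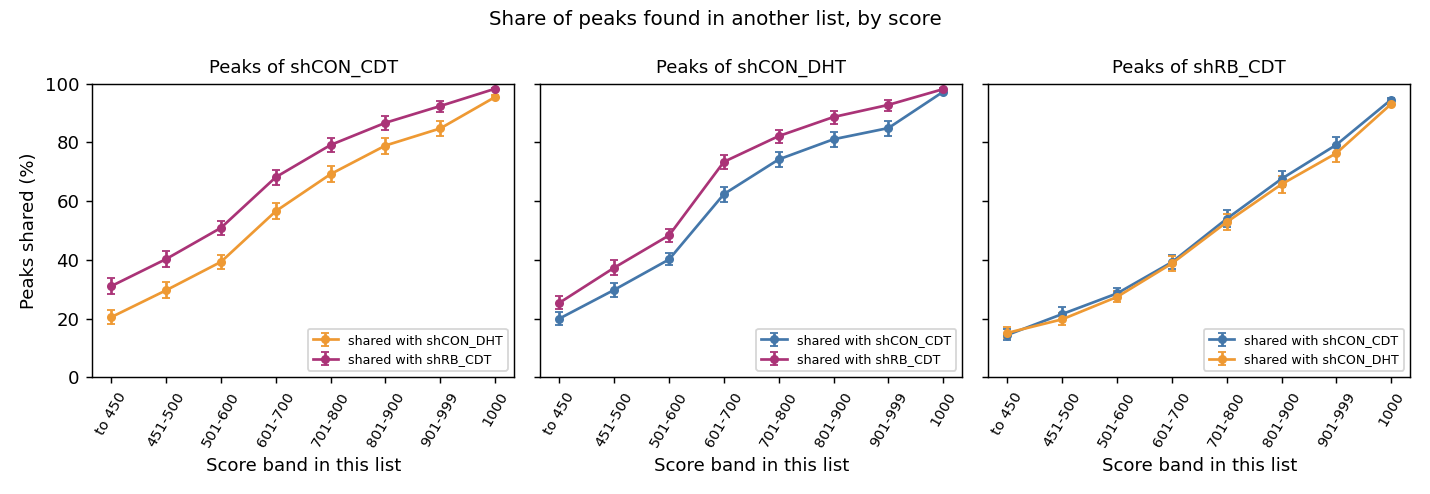
Each panel takes the peaks of 1 list, grouped by their score in that list (horizontal axis, 8 bands), and shows the percentage that overlap a peak of each other list (vertical axis), with exact 95% binomial intervals as bars. Sharing climbs with score in every panel, from 14.4% of the lowest-scoring shRB CDT peaks to 94.6% of those at the cap for the comparison with shCON CDT.

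The larger number of shRB CDT peaks was spread over most chromosomes. Chromosome 3 had 1.35 times (1.22 to 1.49) as many peaks in shRB CDT as in shCON CDT, chromosome 1 had 1.33 times (1.23 to 1.43) and chromosome 5 had 1.31 times (1.17 to 1.46). Chromosome 21 had fewer in shRB CDT, 145 against 178 peaks, a ratio of 0.815 whose interval (0.650 to 1.02) reached 1. Chromosome Y held 24 against 33 peaks, a ratio of 0.727 (0.411 to 1.27). The next lowest autosomes were chromosome 4 at 1.13 (0.990 to 1.28) and chromosome 11 at 1.16 (1.04 to 1.29). These intervals treat peaks as independent counts, and 24 chromosomes were examined.

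The second comparison asked whether the accessible sites of control cells differed after 3 hours of DHT. The shCON DHT list held 800 more peaks than shCON CDT (6.61% more), but they were narrower and covered 11.5% less sequence. Of the shCON CDT peaks, 65.4% (64.5 to 66.2) were also in shCON DHT, against 0.850% at random, and 63.3% (62.5 to 64.2) of shCON DHT peaks were in shCON CDT. The unshared peaks numbered 4728 in shCON DHT and 4190 in shCON CDT. With both lists cut by score to 12096 peaks, the order turned, at 4073 and 4317. The median score percentile of unshared peaks was 24.6 (23.8 to 25.4) within shCON DHT and 23.8 (23.04 to 24.8) within shCON CDT.

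At the score cap, set against the full other list, the difference ran the other way. In the top 50% of each list by score the unshared peaks still numbered 1855 in shCON DHT against 1546 in shCON CDT. That count is a different measure, since both lists were cut and a counterpart below the cut did not count. At the cap, 179 of 3931 shCON CDT peaks (4.55%, 3.92 to 5.25) were absent from shCON DHT, and 96 of 3478 shCON DHT peaks (2.76%, 2.24 to 3.36) were absent from shCON CDT. At the 6240 sites with 1 peak in every list, shCON DHT peaks were 0.896 times (0.889 to 0.904) as wide as shCON CDT peaks. The 5 top-ranked shCON DHT peaks without a shCON CDT counterpart lay on chromosome 18 from 43753355 to 43754770, chromosome 20 from 34741859 to 34743121, chromosome 3 from 51704806 to 51706031, chromosome 2 from 203240452 to 203241666, and chromosome 15 from 32322062 to 32323274. All 5 also overlapped a shRB CDT peak, as did 78 of the 96 at the cap and 30.3% of all 4728, and the one on chromosome 2 was only 0.214 kb from a shCON CDT peak. Of shCON DHT peaks in general, 98.1% at the cap and 69.4% of all overlapped a shRB CDT peak. The 5 top-ranked shCON CDT peaks missing from shCON DHT lay on chromosome 20 from 58513838 to 58515992, chromosome 10 from 27529169 to 27531289, chromosome 4 from 78739857 to 78741853, chromosome 10 from 115438790 to 115440760, and chromosome 21 from 11143671 to 11145479. All 5 were also in shRB CDT, as were 144 of the 179 (80.4%) at the cap and 36.9% of all 4190 shCON CDT peaks missing from shCON DHT. Both shares were below those of shCON CDT peaks in general, of which 98.3% at the cap and 73.2% of all were in shRB CDT.

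By chromosome, the largest ratios of shCON DHT to shCON CDT peak numbers were on chromosome X at 1.29 (1.08 to 1.54), chromosome 13 at 1.28 (1.05 to 1.56) and chromosome 4 at 1.22 (1.08 to 1.39). The ratio was 0.818 (0.473 to 1.40) on chromosome Y, 0.876 (0.702 to 1.09) on chromosome 21, 0.968 (0.816 to 1.15) on chromosome 22 and 0.972 (0.835 to 1.13) on chromosome 20. Chromosome 21 had the lowest autosomal ratio in both comparisons, which share the shCON CDT list.

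**Figure D3:**
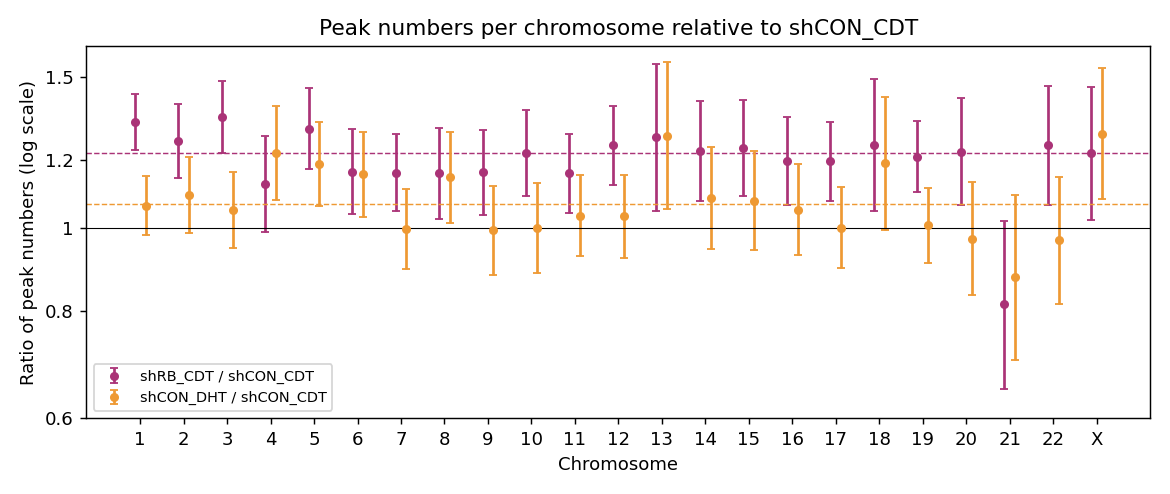
Points give the ratio of peak numbers to shCON CDT (vertical axis, log scale) for shRB CDT and shCON DHT on each autosome and chromosome X (horizontal axis), with exact 95% intervals as bars and dashed lines at the ratio over the whole genome. Chromosome 21 lies lowest for both, at 0.815 for shRB CDT and 0.876 for shCON DHT.

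The third comparison set the RB-depleted cells without hormone beside control cells with DHT. Of the shCON DHT peaks, 69.4% (68.6 to 70.2) were in shRB CDT, more than the 63.3% that were in shCON CDT, and with the lists cut to one length the shares were 68.9% and 66.3%. Of the shRB CDT peaks, 57.9% (57.1 to 58.7) were in shCON DHT, against 59.1% in shCON CDT, an order that turned in the top 50% of each list, with 68.1% and 67.6%. By sequence, shRB CDT and shCON DHT had 7.49 Mb in common, against 8.42 Mb for shRB CDT with shCON CDT and 6.74 Mb for shCON DHT with shCON CDT. Over the union of covered bases these were 0.421, 0.462 and 0.442, a measure that is lowered where the covered lengths are unequal, as in the first of these pairs (15.0 and 10.3 Mb). Unshared peaks numbered 6230 in shRB CDT and 3944 in shCON DHT, with median score percentiles of 26.4 and 22.4. In lists cut to one length they numbered 4134 and 3765.

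Of the unshared peaks of this last pair, 24.0% in shRB CDT and 16.4% in shCON DHT overlapped a shCON CDT peak. At the score cap these shares were 72.7% (261 of 359) and 72.3% (47 of 65). They were below those of all peaks at the cap, of which 94.6% in shRB CDT and 97.2% in shCON DHT overlapped a shCON CDT peak. The 5 top-ranked shRB CDT peaks absent from shCON DHT lay on chromosome 3 from 184079149 to 184081440, chromosome 10 from 20104393 to 20106587, chromosome 11 from 61582490 to 61584661, chromosome 4 from 78739717 to 78741831, and chromosome 1 from 151810753 to 151812861. The 5 top-ranked shCON DHT peaks absent from shRB CDT lay on chromosome 19 from 7683868 to 7685172, chromosome 1 from 101490771 to 101492041, chromosome 4 from 122790859 to 122792070, chromosome 2 from 71356768 to 71357783, and chromosome 19 from 52429805 to 52430764. All 10 overlapped a shCON CDT peak.

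Sites absent from shCON CDT were compared between the RB-depleted and the DHT-treated cells. Of 5978 regions listed in shRB CDT and not in shCON CDT, and 4538 listed in shCON DHT and not in shCON CDT, 1241 were the same, which is 20.8% of the former and 27.3% of the latter. In lists cut to one length 979 were the same, 25.8% of 3796 and 24.9% of 3926, so the order of the shares turned. In the top 50% of each list 890 were the same, 37.3% of 2384 and 49.6% of 1796. There the shCON CDT list was cut too, at a score of 760. These numbers thus include regions with a lower-scoring shCON CDT peak, and are not shares of sites absent from the full list. For the full lists, the expected overlap planned in advance, that of independent sets among all 21031 regions, was 1290 against the 1241 found. It cannot serve as a fair expectation, since every region absent from shCON CDT was by construction in at least 1 of the other lists. Part of the overlap can also come from the shared shCON CDT list, whose replicates could not be split. Of the 281 shRB CDT peaks at the score cap that were absent from shCON CDT, 65.1% (59.2 to 70.7) overlapped a shCON DHT peak, and of the 96 such shCON DHT peaks 81.3% (72.0 to 88.5) overlapped a shRB CDT peak. Both shares were below those of all peaks at the cap, of which 93.1% overlapped shCON DHT in shRB CDT and 98.1% overlapped shRB CDT in shCON DHT. Regions missing from both shRB CDT and shCON DHT numbered 2642 of the 11756 in shCON CDT, where independent absence would give 1103, or 2120 within bands of score and width. The ratio of observed to independent joint absence was thus 2.40, or 1.25 within bands, and it was also above 1 with shCON DHT (2.30, or 1.22) or shRB CDT (1.88, or 1.16) as the reference list.

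The genomic surroundings of the regions held by 1 list differed between conditions. Regions of shRB CDT only had a mean of 4.51 common regions within 500 kb, above all 10000 random sets of single-list regions, whose central 95% ran from 4.003 to 4.16. Regions of shCON DHT only had a mean of 3.47, below all 10000 random sets (3.98 to 4.19). Regions of shCON CDT only had a mean of 4.09, inside the random range (3.96 to 4.21). As the random sets were drawn from these 3 classes together, the departures of the classes from random are not independent of each other. Random sets treat regions as independent, although regions of a class cluster. Resampling whole blocks of 5 Mb gave wider intervals for the difference from all single-list regions, 0.33 to 0.53 for shRB CDT and -0.77 to -0.48 for shCON DHT. No common region lay within 500 kb of 18.3% (17.0 to 19.7) of the shCON DHT regions, 14.0% (12.7 to 15.3) of the shCON CDT regions and 10.6% (9.71 to 11.5) of the shRB CDT regions. Within the top 50% of each list by score, the differences from random shrank to -0.15 for shCON DHT and 0.09 for shRB CDT, at the 2.52 and 96.1 percentiles. These measures were chosen after the data were examined.

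**Figure D4:**
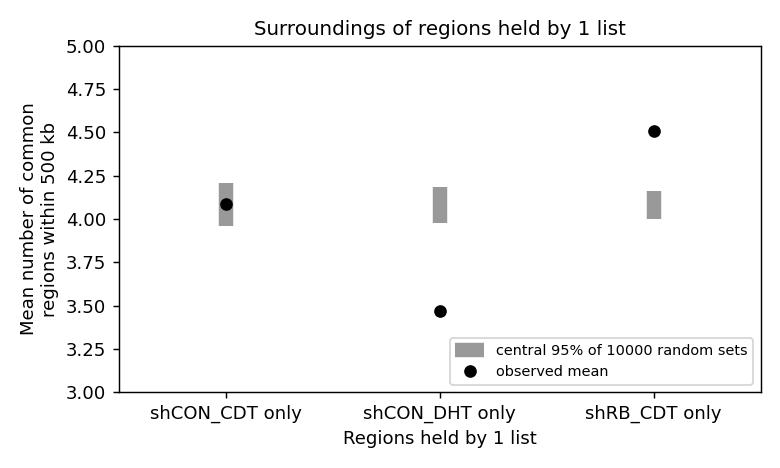
Black points give the mean number of regions common to all 3 lists within 500 kb (vertical axis) of the regions held by only 1 list (horizontal axis), and grey bars the central 95% of 10000 random sets of the same size. The shCON DHT point, 3.47, lies below its bar and the shRB CDT point, 4.51, above its bar.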

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

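Under each setting except autosomes only, the shares of peaks that overlapped another list moved beyond their counting intervals for at least 5 of the 6 pairs. The unshared peaks had a median score percentile of at most 29.3 in each setting, ranked within the lists as cut. In the top 50% of each list the lowest scores were 760 in shCON CDT, 690 in shCON DHT and 784 in shRB CDT. A low percentile in that setting is therefore not a low rank in the full list. Values follow the order shCON CDT in shCON DHT, shCON CDT in shRB CDT, shCON DHT in shCON CDT, shCON DHT in shRB CDT, shRB CDT in shCON CDT, and shRB CDT in shCON DHT. With a 50% reciprocal overlap the shared percentages were 57.2, 65.7, 53.7, 57.5, 53.7 and 50.1, and the median score percentiles of the unshared peaks were 27.4, 24.1, 28.4, 27.3, 27.8 and 29.3. With peaks within 500 bp counted as shared they were 67.3, 74.6, 65.0, 70.8, 60.6 and 59.5. With peaks reset to 500 bp they were 63.9, 70.7, 60.8, 66.6, 57.5 and 56.6, and the percentiles that moved were 22.2, 25.8 and 23.4 for shCON CDT in shRB CDT and for shCON DHT in either other list. In the top 50% of each list they were 74.4, 83.4, 71.3, 80.4, 67.6 and 68.1, unshared peaks numbered 1546, 1006, 1855, 1265, 2400 and 2358, and the percentiles of the first 3 pairs were 27.1, 22.8 and 25.8. By construction that left fewer regions: 669 in shCON CDT only, 906 in shCON DHT only, 1494 in shRB CDT only, 328 in both shCON lists, 843 in both CDT lists and 4117 in all 3. With lists cut to 12096 peaks, the shared percentages were 64.3, 69.4, 66.3 and, for the last 2 pairs, 68.3 and 65.8, and the percentiles were 22.03 for the second pair, 23.7 for the third, 22.3 for the fifth and 23.8 for the last. In those cut lists the unshared shRB CDT peaks fell to 3838 and 4134, and regions of shRB CDT only to 2817, fewer than the 2930 of shCON CDT only; equal lengths bring the 2 directions close by construction. No paired analysis was possible because each list pools replicates 1 and 2, and for the same reason no replicate could be left out. Other settings set in advance for promoter windows, gene lists and motifs were not run for want of an hg19 genome or annotation. Depth is unknown, so whether an unlisted site was closed or only undersampled cannot be read from these lists.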

Other observations

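The tests of peak width and of joint absence by reference list, the neighbour distances, the block resampling, the windows and the chromosome relation were chosen after the data were seen; the tests with matched random sets and within bands of score and width were set before their results were seen. Regions of a single condition were clustered along the genome. A second region of the same class lay within 50 kb of 33.8% of shRB CDT regions, 30.5% of shCON DHT regions and 27.6% of shCON CDT regions, against means of 28.7%, 21.4% and 17.7% when the 3 labels were shuffled 1000 times among single-list regions. The densest 1 Mb window for shRB CDT was on chromosome 5 from 1000001 to 2000000, with 15 shRB CDT regions among 25, where 3 regions were in shCON CDT only and 1 was in all 3 lists. On chromosome 1 from 155000001 to 156000000, 13 of 33 regions were in shRB CDT only and 0 in shCON CDT only. The densest for shCON DHT was on chromosome 19 from 45000001 to 46000000, with 9 regions of that list only, 5 of shCON CDT only and 4 of shRB CDT only. Chromosome 11 from 10000001 to 11000000 held 8 of shCON DHT only, with 1 of shCON CDT only and 0 of shRB CDT only. For shCON CDT, chromosome 19 from 1 to 1000000 held 14 of 38, with 10 of shRB CDT only and 3 of shCON DHT only, and chromosome 21 from 10000001 to 11000000 held 9 of its 17 regions, with 0 in all 3 lists. Shuffled labels gave a densest window of 14, 11 and 9 regions at the median for shRB CDT, shCON DHT and shCON CDT, so the windows for shRB CDT and shCON DHT do not stand apart by their counts of 15 and 9. The 14 of shCON CDT equals the highest of the shuffles.

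Across the 22 autosomes, the density of shCON CDT peaks followed that of protein-coding genes (Pearson r = 0.985, Spearman rho = 0.921), and without chromosomes 17 and 19, the farthest from the median gene density, r was 0.920. The ratio of shCON DHT to shCON CDT peak numbers was lower on gene-dense autosomes (r = -0.39, rho = -0.52, and r = -0.54 without chromosomes 17 and 19). The ratio for shRB CDT showed little relation (r = 0.04, rho = -0.11). Without chromosome 21, the lowest autosome in both ratios, r was -0.11 and rho -0.23 for shRB CDT. For shCON DHT they were then -0.49 and -0.65. Chromosomes are not replicates of a condition, so no p-value is given.

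The first pattern is the larger number of peaks in shRB CDT and shCON DHT than in shCON CDT. A candidate explanation is a generally more sensitive list, from deeper or cleaner libraries. It was taken to widen peaks at sites open in every condition too, a premise that was not tested. For shRB CDT the median width ratio at such sites was 1.04 (1.03 to 1.04), so this explanation stays open, beside an effect of RB depletion. For shCON DHT the ratio was 0.896 (0.889 to 0.904), opposite to that prediction. The prediction was written after the narrower peaks of the whole shCON DHT list could be seen, and depth is unknown. The ratio therefore cannot decide the question for that list. Which sets of peaks were compared for the IDR threshold is not stated, and how their agreement bears on peak number was not tested.

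The second pattern is that shCON DHT regions lay in sparse surroundings. If low-scoring or narrow peaks were the cause, random single-list regions matched on score percentile and width would have as few common neighbours. Their mean was instead 3.96 (3.86 to 4.06) against the observed 3.47, and resampled blocks put the difference at -0.61 to -0.38. Score percentiles are ranks within 1 list, however, so this match does not make peaks of different lists equally strong. It cannot decide the question, and low-scoring peaks stay open as a cause. If whole chromosomes differed, as copy number would give, sets matched on chromosome would have as few common neighbours. Their mean was 3.92 (3.83 to 4.02), and blocks put the difference at -0.54 to -0.33. No sets were matched on score, width and chromosome together. Both shCON groups were LNCaP cells with the control hairpin, yet shCON CDT regions had a mean of 4.09. That would argue against copy number within chromosomes for the contrast of these 2 groups only if both had the same copy number. Copy number was not measured, so it stays open, also for the contrast with shRB CDT. Differences in the GC content that each library favoured stay open, as does an effect of DHT itself. The distance of these sites from genes was not measured. The pattern kept its direction with neighbours counted within 100 kb (-0.13 against random) or 2000 kb (-1.69), but was at the 2.52 percentile in the top 50% of the lists (-0.15).

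The third pattern is that sites missing from shRB CDT tended to be missing from shCON DHT too, 2.40 times (2.34 to 2.45) as many as independent absence would give. Low score and narrow width account for much of the pattern, since within bands of both the ratio was 1.25 (1.22 to 1.26). That lies above the 1.1 set as the bound for their being the whole cause. Peaks can still differ in score and width within a band, and peaks at the score cap are tied. The ratio therefore cannot tell whether score and width are the whole cause. For any rest a candidate explanation is peaks private to 1 list in every condition. The odds ratio of joint absence was 23.9 (21.4 to 26.6) with shCON CDT as the reference, against 33.6 (30.2 to 37.4) for shCON DHT and 19.5 (17.9 to 21.2) for shRB CDT. By this measure joint absence was not particular to shCON CDT. The odds ratios were computed without bands, so they include what score and width give. A region missing from both other lists is private to its list by definition, so they cannot test this explanation. The ratio within bands was in excess with each list as the reference too. It was 1.25 for shCON CDT, 1.22 (1.199 to 1.23) for shCON DHT and 1.16 (1.15 to 1.17) for shRB CDT. The intervals for shCON CDT and shCON DHT overlap, and the odds ratio put shCON DHT first, so the order of these 2 lists is not settled. A response common to RB depletion and DHT stays open, as the shared control list could not be split.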
